A study of Homo sapiens with 12 samples.

How the data were processed

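Biotin-labelled RNA from SNB19 and SF539 glioma cells was measured on 12 Affymetrix arrays, 2 for each of 6 groups, per the labels. Cells received scramble siRNA, PARK2 siRNA1 or PARK2 siRNA2 by lipid transfection and were collected after 48 h, per the labels. The deposited values are on the log2 scale, from 2.01 to 14.1, and Partek is named per the submitters' processing notes. The background correction, normalization, summary method and genome build are not given in the sources used here. Sorted values of the probe sets differed between arrays by up to 0.302. The values carry no detection call. Genes near the lower quartile of the arrays, 3.93 to 4.02, have little signal over background, and their changes are bounded by it.

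The table held 16376 probe sets. Of these 14038 had 1 gene, 792 several and 1546 none in the gene table used, and a probe set with several genes named none. PARK2 is not analysed here. Symbols of 14028 probe sets were matched through Entrez identifiers to the RefSeq table of assembly GRCh38.p14, which served only for names and for which genes neighbour each other. Each gene was represented by its brightest probe set over all arrays, giving 8545 genes, of which 3361 had several probe sets.

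A model with 6 groups was fitted to all arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 6 residual and 3.65 prior degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Using all groups shares 1 estimate of the spread. The PARK2 effect in a line was the mean of both siRNAs minus scramble, and the effect over both lines was the mean of those. Each siRNA against scramble, siRNA2 against siRNA1, the difference between lines and the lines with scramble were also tested. Errors of fold changes are standard errors of the fit. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, on ranks and with fry. The 29 lists were G1/S regulators, DNA replication, mitosis, p53 targets, mitophagy, oxidative phosphorylation, proteasome, unfolded protein response, ATF4 targets, interferon-stimulated genes, NF-kB genes, cholesterol and fatty acid synthesis, hypoxia, glycolysis, Wnt targets, MAPK-induced genes, histones, extracellular matrix, YAP/TAZ targets, lysosome, ribosome biogenesis, apoptosis, heat shock, NRF2 targets, RNA interference, glial lineage, leukocytes, endothelium and epithelium.

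In each comparison of the mean of both PARK2 siRNAs with scramble the genes named are the 10 largest changes up and the 10 down among called genes with the same sign for both siRNAs (in both lines for the mean of lines). In the other comparisons, each siRNA alone included, they are the 5 largest up and the 5 down. Up to 4 members by smallest p are named from each called list and from the G1/S and mitophagy lists. CDK4, CCNE1, DDIT3, FABP7, S100B, IRF7 and IFNB1 in SNB19, the genes of the scan of neighbouring genes, DKK1, NT5E, CXCL8 and CCL5 with the PARK2 siRNAs, and CDKN2A, SLC2A1, H2BC21 and S100B between the lines were chosen after their values were seen. Beside the group means, the levels of IFIT1 and IFIT3 in both lines, of FAS, ESM1, CCL20 and IL24 in SNB19 and of CRYAB and MMP7 in SF539, and the changes of IFI27, BST2, PSMB9, IFITM1, ISG15, CRYAB and MMP7 in SF539 were likewise chosen after their values were seen.

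The gene test was tested on simulated data with 8545 genes. For the PARK2 siRNAs in SNB19, 79.1% of 67 genes changed 1.5-fold, 98.5% of 67 changed 2-fold and 100% of 66 changed 4-fold were recovered, with 9 false calls among 194. For SF539 these shares were 83.6%, 94.0% and 100%, with 8 false calls among 193. The list test for SNB19 called the glycolysis list, shifted by -0.5, and 0 of the others. The simulated noise was independent between genes and had the same spread in all groups. In the data the median SD between replicates was 0.132 for SF539 siRNA2 and 0.0616 to 0.0852 in the other groups. The simulated rates may therefore not hold for SF539, nor the list result where genes vary together.

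Alternatives were a replicate block, the arrays of 1 line alone, quantile normalization, median centring, the dimmest 40% of genes left out, the mean of probe sets, every probe set on its own, a trended robust prior, array weights, a 1.5-fold minimum and leaving out each array, whose lone partner is then assumed to vary like the other groups. For shared controls 100 simulations of unchanged groups were drawn, and each siRNA was also set against a scramble array of its own. Plots used matplotlib 3.10.9.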

Results

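Gene expression was measured on 12 Affymetrix arrays from SNB19 and SF539, 2 established glioma cell lines, after transfection with a scramble siRNA or with 1 of 2 siRNAs against PARK2, the gene of parkin, a ubiquitin ligase that marks damaged mitochondria for removal. Each of the 6 groups held 2 arrays. Values were on the log2 scale, and 8545 genes were tested. Array medians lay between 5.94 and 6.14. Replicate arrays correlated across probe sets, which are not independent replicates, with r from 0.991 to 0.998, the lowest being the SF539 siRNA2 pair. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. The PARK2 level was not analysed here, so the knockdown itself was not checked. Without an untransfected sample among the arrays, a difference from scramble can lie with the scramble samples or with the PARK2 siRNAs.

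The first question was which genes change in SNB19 when PARK2 is targeted. With the PARK2 siRNAs, interferon-stimulated genes were far lower than with scramble. IFI27 fell by 8.66 ± 0.08 on the log2 scale (SE, 2 arrays per group, limma adjusted p = 4.96e-12), from 12.96 ± 0.02 with scramble to 3.98 ± 0.01 with siRNA1 and 4.62 ± 0.18 with siRNA2 (SD, n = 2 each). The antiviral genes BST2, OAS1, MX1 and RSAD2 changed by -6.52, -6.34, -6.32 and -6.19. IFIT3, IFIT1, IFI44L, the immunoproteasome subunit PSMB9 and the membrane protein gene IFITM1 changed by -6.02, -5.84, -5.45, -5.98 and -5.95. IFITM1 shares sequence with IFITM2 and IFITM3, so its own share of the signal is uncertain. Of 26 measured members of the interferon list 25 fell and 1, IRF7, rose by 0.64, with a scramble mean of 3.56 below the lower quartile of the arrays and a call lost without SNB19 scramble replicate 1 (a change of 0.42, adjusted p = 0.199) or siRNA1 replicate 2 (adjusted p = 0.0511). The median change of the list was -4.69 (camera adjusted p = 3.11e-32), and the call held (adjusted p = 0.0295 with an estimated correlation). The counts were 25 and 1 adjusted over the list alone.

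Among genes called with the same sign for both siRNAs, the largest rises in SNB19 were those of SCRG1, SERPINA3 and GFAP. SCRG1 rose by 4.48 ± 0.15 (limma adjusted p = 1.91e-08), the acute-phase protease inhibitor gene SERPINA3 by 3.95 ± 0.13 (limma adjusted p = 1.34e-08) and the astrocyte filament gene GFAP by 3.58 ± 0.16 (limma adjusted p = 1.53e-07). The probe sets of GFAP differed in sign, and their mean changed by 1.75. The small heat shock protein gene CRYAB rose by 3.19, the chemokine gene CCL2 by 3.11, the matrix protease gene MMP7 by 2.95, the aconitase gene ACO1 by 2.90, the endothelin receptor gene EDNRB by 2.64, SPARCL1 by 2.40 and EFHD1 by 2.30. The glial and neural list was not called (adjusted p = 0.662), with 3 of 16 members higher, FABP7 and S100B by 1.33 and 1.00, and 3 lower (4 and 3 adjusted over the list alone).

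Genes induced by low oxygen fell together in SNB19. Of 17 hypoxia-induced genes 15 fell, among them ADM, STC1 and the angiogenic factor gene VEGFA with changes of -2.59, -1.85 and -1.41 (list adjusted p = 6.78e-10, and adjusted p = 0.312 with an estimated correlation). All 17 fell when adjusted over the list alone. Of 20 glycolysis genes 12 fell, HK2 and the glucose transporter gene SLC2A1 changing by -1.55 and -0.86 (list adjusted p = 0.000272, and adjusted p = 0.369 with an estimated correlation), and 12 adjusted over the list alone. Of 22 ATF4 targets and amino acid supply genes 15 fell and 2 rose, STC2, SLC7A5 and SLC3A2 changing by -2.68, -1.95 and -1.62 (list adjusted p = 0.000132, and adjusted p = 0.572 with an estimated correlation), with 15 and 2 adjusted over the list alone. The unfolded protein response list was not called (adjusted p = 0.772), although DDIT3, a stress transcription factor gene, fell by 2.42. Of 14 replication-dependent histones 9 fell, H2BC21 and H2BC12 changing by -2.76 and -2.63 (list adjusted p = 9.14e-05, and adjusted p = 0.312 with an estimated correlation), and 10 adjusted over the list alone. Near-identical histone genes can share probes. Of 17 MAPK-induced genes 12 fell and 2 rose, the feedback regulators DUSP4 and SPRY2 changing by -1.70 and -1.34 (list adjusted p = 0.00053, and adjusted p = 0.369 with an estimated correlation), with 13 and 3 adjusted over the list alone.

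Cell cycle and survival lists in SNB19 were examined next. Of 29 DNA replication genes 10 rose and none fell, MCM6 by 1.26 and RFC5 by 1.15, or 0.63 as the mean of the probe sets of RFC5 (list adjusted p = 0.00053, and adjusted p = 0.716 with an estimated correlation), and 13 adjusted over the list alone. The list of G1/S cyclins, CDKs and their inhibitors was not called (adjusted p = 0.111), with 9 of 24 members higher and 3 lower. The counts were 10 and 3 adjusted over the list alone. CCNE2 rose by 0.92, CDK4 by 0.54 and CCNE1 by 0.53, the last losing its call without scramble replicate 1 or 2 (adjusted p = 0.0668 and 0.0672). The CDK inhibitor gene CDKN1A and CCND3 changed by -1.41 and -1.06. Of 11 p53 targets 4 fell, the death receptor gene FAS and GADD45A changing by -1.74 and -1.11 (list adjusted p = 0.00349, and adjusted p = 0.135 with an estimated correlation), and of 19 apoptosis regulators 8 fell, PMAIP1 and CASP8 changing by -1.03 and -0.79 (list adjusted p = 0.00349, and adjusted p = 0.135 with an estimated correlation). These counts were 4 and 8 adjusted over the list alone. Of 16 NRF2 targets 9 rose and 2 fell, AKR1C3, which has near-identical relatives, rising by 1.08 (list adjusted p = 0.0239, and adjusted p = 0.484 with an estimated correlation), and the call was lost with quantile normalization (adjusted p = 0.0967) and without either SF539 siRNA2 array (adjusted p = 0.0524). The NRF2 list averaged 9.99 with scramble, 10.43 with siRNA1 and 10.07 with siRNA2, so its rise lay mostly with siRNA1. With dim genes left out the NRF2, p53 and cholesterol calls were lost (adjusted p = 0.0757, 0.0762 and 0.077), the last also with the mean of probe sets (adjusted p = 0.0846). Of 23 cholesterol and fatty acid genes 6 rose and 1 fell, ACACA rising by 0.89 (0.21, adjusted p = 0.0692, with the mean of its probe sets) and SREBF1 changing by -1.30 (list adjusted p = 0.0239, and adjusted p = 0.694 with an estimated correlation). Adjusted over the list alone, 9 and 2 NRF2 targets and 6 and 1 cholesterol genes passed. The mitophagy list was not called (adjusted p = 0.738), with 4 of 26 members higher and 8 lower, and 5 and 9 adjusted over the list alone. TOMM20 rose by 0.70 (0.38 as the mean of its probe sets), and BNIP3 and the autophagy receptor gene OPTN changed by -0.90 and -0.66.

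In all, 2806 genes passed in SNB19, 1322 higher and 1484 lower, and of the 114 that changed at least 4-fold 18 were higher and 96 lower. Centring each array on its median moved the median of all genes from -0.01 to 0.12 and the share of higher calls from 47.1% to 68.3%, and the named changes, all over 0.5, exceed that shift. The count was 1741 without SNB19 scramble replicate 1 and 1186 with a 1.5-fold minimum.

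**Figure D1:**
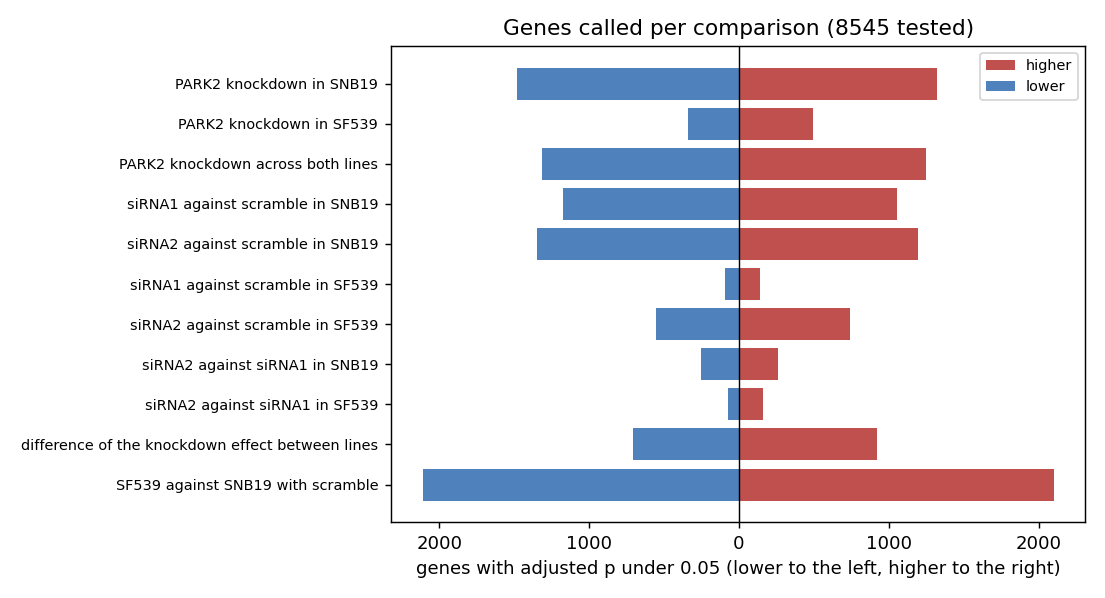
Number of genes with adjusted p under 0.05 in each comparison on the horizontal axis, lower genes to the left of 0 in blue and higher genes to the right in red. The PARK2 siRNAs against scramble gave 2806 genes in SNB19 and 839 in SF539.

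The same question in SF539 gave fewer calls, CCL2 rising and ESM1 falling the most among genes called with the same sign for both siRNAs. CCL2 rose by 3.40 ± 0.29 (limma adjusted p = 0.000204), from 4.24 ± 0.22 with scramble to 6.11 ± 0.35 with siRNA1 and 9.17 ± 0.92 with siRNA2 (SD, n = 2 each). CCN4 rose by 2.44 ± 0.33, the matrix protein genes MATN2 and COL3A1 by 2.40 ± 0.29 and 2.26 ± 0.26, the kinase gene DAPK1 by 2.25, GPR183 by 2.25, OLFML2B by 2.20, the collagen gene COL1A1 by 2.15, the fatty acid desaturase gene SCD by 2.06 and the adhesion molecule gene VCAM1 by 2.03. Probe sets of DAPK1 and of COL1A1 differed in sign, and the means of the probe sets of CCN4, DAPK1 and COL1A1 changed by 1.35, 1.10 and 1.34. ESM1, which encodes a secreted proteoglycan, fell by 3.04 ± 0.28 (limma adjusted p = 0.000281), and the decoy receptor gene IL13RA2 and MN1 changed by -2.31 and -1.58. The cytokine genes CXCL11, IL24, CXCL3, CXCL10 and CCL20 changed by -2.41, -2.23, -1.93, -1.87 and -1.65. The interferon beta gene IFNB1 fell by 1.88 (limma adjusted p = 0.000943) and ISG20 fell by 1.75 ± 0.06 (limma adjusted p = 1.77e-06).

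Of 26 interferon-stimulated genes 6 fell in SF539 and none rose, RSAD2, OAS1 and TRIM22 changing by -1.22, -0.70 and -0.59 (list adjusted p = 1.82e-06, and adjusted p = 0.442 with an estimated correlation), and 10 fell adjusted over the list alone. IFI27 stood at 12.88, 12.74 and 12.80 with scramble, siRNA1 and siRNA2. Of 23 cholesterol and fatty acid genes 13 rose and none fell, the transcription factor gene SREBF1 by 1.38, ACACA by 0.71 and ACAT2 by 0.56 (list adjusted p = 1.93e-09, and adjusted p = 0.442 with an estimated correlation), with 15 and 1 adjusted over the list alone. Of 17 hypoxia-induced genes 6 rose, DDIT4 by 1.58, ADM by 0.89 and BNIP3 by 0.77 (list adjusted p = 9.45e-06, and adjusted p = 0.683 with an estimated correlation), and of 20 glycolysis genes 3 rose, SLC2A1 by 0.85 and HK2 by 0.58 (list adjusted p = 0.0362, and adjusted p = 0.75 with an estimated correlation). These counts were 7 and 4 adjusted over the list alone. Without scramble replicate 1 the calls of OAS1 and HK2 were lost (adjusted p = 0.0508 and 0.0711), and the glycolysis call was lost with dim genes left out (adjusted p = 0.0743). Of 26 matrix and mesenchymal genes 7 rose and 1 fell, COL1A2 rising by 1.95 and MMP2 by 1.29 (list adjusted p = 0.000508, and adjusted p = 0.75 with an estimated correlation), with 11 and 3 adjusted over the list alone. The SF539 siRNA2 arrays stood apart in this list, replicate 2 exceeding replicate 1 by a median of 1.08, and in the hypoxia list, by a median of 0.55. Without replicate 2 the median change of these lists moved from 0.55 to 0.31 and from 0.35 to 0.17.

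Lists with few called members in SF539 were ribosome biogenesis, with 3 of 14 lower and the polyamine enzyme gene ODC1 falling by 0.78 (list adjusted p = 0.00832, and adjusted p = 0.683 with an estimated correlation), MAPK-induced genes, with 3 of 17 lower, CCND1 and DUSP4 by changes of -1.09 and -0.45 (list adjusted p = 0.0135, and adjusted p = 0.683 with an estimated correlation), and proteasome subunits, with 1 of 27 lower, PSMD8, which fell by 0.27 (list adjusted p = 0.0311, and adjusted p = 0.966 with an estimated correlation). The counts were 3, 7 and 0 lower adjusted over the list alone. With scramble, siRNA1 and siRNA2 the ribosome biogenesis list averaged 9.83, 9.80 and 9.47 and the proteasome list 11.40, 11.41 and 11.18. The decreases of these lists thus lay with siRNA2, and siRNA1 left their averages nearly unchanged. The MAPK-induced list averaged 8.49, 8.28 and 8.30. The G1/S list was not called (adjusted p = 0.81), with 3 of 24 members higher and 3 lower, and 3 and 5 adjusted over the list alone. CDKN1C rose by 1.26, and CDKN1A fell by 0.65. The mitophagy list was not called (adjusted p = 0.877), with 1 of 26 members higher and 2 lower, also when adjusted over the list alone, and PINK1, the kinase gene upstream of parkin, fell by 0.45 (limma adjusted p = 0.0437). PINK1 and PSMD8 each lost their call without any 1 array other than those of SF539 siRNA2 (adjusted p from 0.0586 to 0.257 and from 0.0561 to 0.203), ODC1 without scramble replicate 1 (adjusted p = 0.0639), CDKN1A without scramble replicate 1 or 2 (adjusted p = 0.0875 and 0.0687) and DUSP4 without scramble replicate 1 or 2 or siRNA1 replicate 2 (adjusted p = 0.11, 0.0729 and 0.0529). With array weights PINK1 and PSMD8 did not pass (adjusted p = 0.0568 and 0.0881), nor did PINK1 or the proteasome list with the mean of probe sets (adjusted p = 0.103 and 0.0725). Without SF539 scramble replicate 2 the calls of the proteasome, MAPK, glycolysis and ribosome biogenesis lists were lost (adjusted p = 0.132, 0.132, 0.256 and 0.119). The proteasome call was also lost without siRNA1 replicate 2 or siRNA2 replicate 2 (adjusted p = 0.0633 and 0.433), glycolysis without siRNA1 replicate 2 or siRNA2 replicate 1 (adjusted p = 0.078 and 0.0585) and MAPK without siRNA2 replicate 1 (adjusted p = 0.0877).

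In SF539, 839 genes passed, 496 higher and 343 lower, and 15 changed at least 4-fold. Median centring moved the share of higher calls from 59.1% to 46.0%. The count was 371 and 466 without scramble replicates 1 and 2, 488 and 461 without siRNA1 replicates 1 and 2, 1973 and 1378 without siRNA2 replicates 1 and 2, 165 with the 6 SF539 arrays alone and 319 with a 1.5-fold minimum. COL1A1 and IL24 lost their calls without scramble replicate 1 (adjusted p = 0.0551 and 0.109) and replicate 2 (adjusted p = 0.0836 and 0.0547), CXCL3 without replicate 1 (adjusted p = 0.0611) and CXCL10 without replicate 2 (adjusted p = 0.0684). With the 6 SF539 arrays alone COL1A1, COL1A2, VCAM1, IL24, CXCL3, CXCL10, CCND1, CDKN1A, HK2, DUSP4, ODC1, PINK1 and PSMD8 did not pass (adjusted p from 0.0578 to 0.195), nor did MMP2 (adjusted p = 0.050008).

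**Figure D2:**
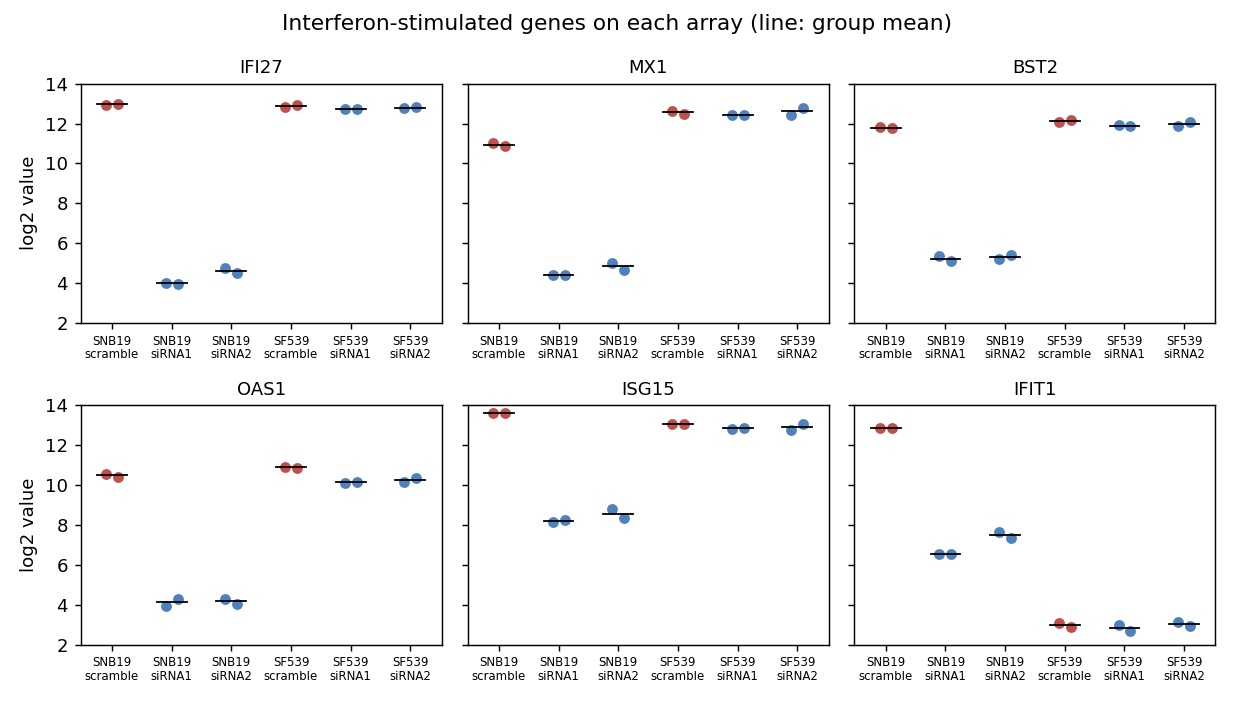
Log2 value of 6 interferon-stimulated genes on each of the 12 arrays, scramble in red and PARK2 siRNAs in blue, with a line at each group mean. IFI27 lies at 12.96 in SNB19 with scramble and at 3.98 and 4.62 with the PARK2 siRNAs, whereas the SF539 groups lie between 12.74 and 12.88.

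Each siRNA was then set against scramble on its own, in SNB19 first. IFI27 changed by -8.98 with siRNA1 and -8.34 with siRNA2, BST2 by -6.57 and -6.47, MX1 by -6.53 and -6.11 and OAS1 by -6.36 and -6.33. PSMB9 changed by -6.59 with siRNA1 and RSAD2 by -6.04 with siRNA2. SCRG1 rose by 5.22 and 3.74, SERPINA3 by 4.09 and 3.81 and GFAP by 3.59 and 3.56 (1.79 and 1.72 as the mean of its probe sets). With siRNA1 CHI3L2 rose by 3.21 and ACO1 by 2.99, and with siRNA2 CRYAB rose by 3.58 and the cytokine gene IL11 by 3.42. Compared with scramble, 2228 genes were called for siRNA1 (1057 higher, 1171 lower) and 2540 for siRNA2 (1192 higher, 1348 lower). Median centring moved the median of all genes to 0.10 and 0.14 and the share of higher calls from 47.4% to 66.0% and from 46.9% to 69.2%. The siRNA1 count was 1457 without scramble replicate 1 and 1469 and 1405 without siRNA1 replicates 1 and 2, and the siRNA2 count was 1637 without scramble replicate 1 and 1593 without siRNA2 replicate 2.

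Both siRNAs called 1674 genes in the same direction in SNB19, 776 higher and 898 lower, and 15 in opposite directions. Independent lists would share 147 higher and 185 lower. Unchanged groups simulated against the same controls shared 0, but almost no unchanged gene passes the adjusted threshold. That count was thus set in advance and does not bound what shared controls add. Fold changes of the siRNAs correlated across genes with r = 0.882, against 0.50 simulated for unchanged groups, and their covariance was 0.308 against a simulated 0.011. With a scramble array of its own for each siRNA, an alternative chosen after seeing the data, the covariance was 0.302 and 0.299 and r was 0.849 and 0.834 for the 2 ways round, to which the value simulated with shared controls does not apply. What both scramble arrays have in common stays in that comparison, so part of the excess may come from the shared controls. Without SNB19 scramble replicate 1 the shared genes numbered 1060.

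Each siRNA was set against scramble in SF539 in the same way. With siRNA1 CXCL11, CXCL10, IL24, ESM1 and CCL20 changed by -3.01, -2.94, -2.36, -2.27 and -1.99, and CCL2, MATN2, GPR183, OLFML2B and TMT1A rose by 1.87, 1.56, 1.53, 1.49 and 1.48. The probe sets of TMT1A differed in sign. With siRNA2 CCL2 rose by 4.93, CCN4 by 3.26 (1.83 as the mean of its probe sets), MATN2 by 3.24 and COL3A1 by 3.20, and ESM1, IL13RA2, CXCL3, the collagenase gene MMP1 and SLC22A4 changed by -3.80, -3.11, -2.71, -2.51 and -2.14. POSTN rose by 3.95 ± 1.06 (limma adjusted p = 0.034), its siRNA2 arrays having an SD of 3.22. Its change was 6.22 and 1.67 without siRNA2 replicates 1 and 2 and 1.98 as the mean of its probe sets. POSTN lost its call when any 1 array other than those of SF539 siRNA2 was left out (adjusted p from 0.0509 to 0.132). The siRNA1 calls of IL24 and MATN2 were likewise lost without any 1 of these arrays (adjusted p up to 0.229 and 0.213). CCL2, GPR183, OLFML2B, TMT1A and ESM1 lost theirs without at least 1 SF539 array (CCL2 adjusted p = 0.112 without scramble replicate 1, 0.0689 and 0.178 without siRNA1 replicates 1 and 2, GPR183 0.0942 without scramble replicate 1 and 0.111 without siRNA1 replicate 1, and OLFML2B, TMT1A and ESM1 0.0506, 0.0763 and 0.0763 without siRNA1 replicate 2). With a trended robust prior IL24 with siRNA1 and POSTN with siRNA2 did not pass (adjusted p = 0.0569 and 0.074), nor did TMT1A with the mean of probe sets (a change of 0.42, adjusted p = 0.0722) or IL24 with every probe set tested (adjusted p = 0.0502).

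Compared with scramble in SF539, 233 genes were called for siRNA1 (138 higher, 95 lower) and 1295 for siRNA2 (740 higher, 555 lower). Median centring moved the share of higher calls from 59.2% to 45.1% and from 57.1% to 44.8%. The siRNA1 count was 16 and 60 without siRNA1 replicates 2 and 1, 76 without scramble replicate 1, 802 without either siRNA2 array and 131 to 141 without any 1 SNB19 array. The siRNA2 count was 615 and 797 without scramble replicates 1 and 2 and 2593 without siRNA2 replicate 1. With the 6 SF539 arrays alone 1 gene passed for siRNA1, none of those named, and 308 for siRNA2, without POSTN (adjusted p = 0.151). Both siRNAs called 189 genes in the same direction, 120 higher and 69 lower, and 0 in opposite directions, where 915 and 1870 genes had an unadjusted p under 0.05 with these 6 arrays alone. Independent lists would share 11.95 and 6.17. Simulated unchanged groups shared 0, which was again set in advance and does not bound what shared controls add. The fold changes correlated across genes with r = 0.653, against 0.50 simulated for unchanged groups. This r was 0.748 without siRNA2 replicate 2 and 0.501 without siRNA2 replicate 1. The simulated value is for 2 arrays in each group and does not apply to either. The fold changes had a covariance of 0.0682 against a simulated 0.011. With a scramble array of its own for each siRNA it was 0.0571 and 0.0524, with r of 0.479 and 0.44, and part of the excess may come from what the scramble arrays have in common. The shared genes numbered 14 and 56 without siRNA1 replicates 2 and 1, 69 without scramble replicate 1, 489 and 547 without siRNA2 replicates 1 and 2, and 120 to 125 without any 1 SNB19 siRNA array.

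As the mean of both lines, interferon-stimulated genes were lower and CCL2 was higher with the PARK2 siRNAs than with scramble. No untransfected sample was analysed here. The interferon list had a median of -4.69 in SNB19 but of -0.23 in SF539, where IFI27 and BST2 changed by -0.12 and -0.18 and did not pass (limma adjusted p = 0.441 and 0.295). CCL2 rose by 3.26 ± 0.20 (limma adjusted p = 2.91e-06), ACO1 by 1.91, CRYAB by 1.66, MMP7 by 1.61, OLFML2A by 1.55, the myosin kinase gene MYLK by 1.48, DCLK1 by 1.47, OLFML2B by 1.46, PGAP1 by 1.41 and the heterochromatin protein gene CBX5 by 1.41 (0.80 as the mean of its probe sets). In SF539 CRYAB and MMP7 changed by 0.13 and 0.27, from scramble means of 4.19 and 3.89 near the lower quartile of the arrays, and did not pass (limma adjusted p = 0.437 and 0.558), so their means over both lines rest on SNB19. IFI27, RSAD2, OAS1, BST2 and PSMB9 changed by -4.39, -3.70, -3.52, -3.35 and -3.15, and IFITM1, CXCL10, OASL, ISG20 and ISG15 by -3.09, -3.05, -3.0, -2.97 and -2.71. PSMB9, IFITM1 and ISG15 changed by -0.32, -0.22 and -0.18 in SF539 and did not pass there (limma adjusted p = 0.147, 0.484 and 0.42). Of 26 interferon-stimulated genes 25 fell (list adjusted p = 5.32e-32, and adjusted p = 0.0301 with an estimated correlation). Of 23 cholesterol and fatty acid genes 14 rose and none fell, SCD by 1.32, or 0.86 as the mean of its probe sets, and SQLE by 0.70 (list adjusted p = 9.92e-06, and adjusted p = 0.385 with an estimated correlation). Of 17 MAPK-induced genes 14 fell and 1 rose, and of 14 histones 9 fell (list adjusted p = 0.000249 and 0.000334, and adjusted p = 0.385 with an estimated correlation for both). Of these, 25, 14, 14 and 9 went the same way adjusted over the list alone.

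Further lists were called over both lines. Of 26 matrix genes 12 rose and 3 fell (adjusted p = 0.0142, and adjusted p = 0.855 with an estimated correlation), of 17 hypoxia-induced genes 8 fell (adjusted p = 0.000721, and adjusted p = 0.675 with an estimated correlation) and of 22 ATF4 targets 9 fell and 2 rose (adjusted p = 0.0045, and adjusted p = 0.839 with an estimated correlation). Of 19 apoptosis regulators 9 fell (adjusted p = 0.00179, and adjusted p = 0.12 with an estimated correlation) and of 11 p53 targets 5 fell (adjusted p = 0.0151, and adjusted p = 0.242 with an estimated correlation). Of 29 DNA replication genes 8 rose and 1 fell (adjusted p = 0.0304, and adjusted p = 0.875 with an estimated correlation), of 52 oxidative phosphorylation genes 9 rose (adjusted p = 0.0446, and adjusted p = 0.88 with an estimated correlation), and of 20 glycolysis genes 5 fell and 1 rose (adjusted p = 0.0446, and adjusted p = 0.714 with an estimated correlation). Adjusted over the list alone, 13 matrix genes rose and 3 fell, 8 hypoxia-induced genes, 12 apoptosis regulators and 6 p53 targets fell, 9 ATF4 targets fell and 2 rose, 8 DNA replication genes rose and 1 fell, 6 oxidative phosphorylation genes rose, and 5 glycolysis genes fell and 1 rose. With scramble, siRNA1 and siRNA2 the oxidative phosphorylation list averaged 11.07, 11.09 and 11.24 in SNB19 and 11.07, 11.17 and 11.04 in SF539. Its average was thus not higher with every siRNA in both lines. The means of both lines join opposite changes for the hypoxia list, with medians of -0.90 in SNB19 and 0.35 in SF539, and for glycolysis, with -0.35 and 0.086. ATF4 targets, DNA replication genes, histones and p53 targets, not called in SF539, had medians of 0.0017, -0.048, -0.026 and -0.18 there. The difference between the lines passed for each of these 6 lists (adjusted p = 1.7e-13, 1.34e-05, 0.000133, 0.000116, 8.55e-05 and 0.0196, and adjusted p = 0.289, 0.323, 0.593, 0.672, 0.323 and 0.289 with an estimated correlation), for p53 targets not with dim genes left out (adjusted p = 0.199). Apoptosis regulators were not called in SF539 (adjusted p = 0.0667), nor matrix genes in SNB19 (adjusted p = 0.391), and their difference between the lines did not pass (adjusted p = 0.15 and 0.118). The oxidative phosphorylation call was lost with quantile normalization (adjusted p = 0.228) and without SNB19 scramble replicate 2, siRNA1 replicate 2 or siRNA2 replicate 1 (adjusted p = 0.0707, 0.0634 and 0.0753) or SF539 scramble replicate 1 or 2, siRNA1 replicate 2 or siRNA2 replicate 1 (adjusted p = 0.0655, 0.0679, 0.0503 and 0.465). The glycolysis call was lost with median centring (adjusted p = 0.0571) and without SNB19 scramble replicate 1, siRNA1 replicate 2 or siRNA2 replicate 1 (adjusted p = 0.106, 0.0642 and 0.0957) or SF539 scramble replicate 1, siRNA1 replicate 1 or siRNA2 replicate 1 (adjusted p = 0.106, 0.0689 and 0.0772), and the DNA replication call without SNB19 scramble replicate 2 or SF539 siRNA2 replicate 1 (adjusted p = 0.058 and 0.465). With dim genes left out the oxidative phosphorylation, glycolysis, DNA replication, p53 and matrix calls were lost (adjusted p = 0.147, 0.0829, 0.0829, 0.121 and 0.0829), the first also with the mean of probe sets (adjusted p = 0.0971).

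A total of 2561 genes passed over both lines, 1245 higher and 1316 lower, and median centring moved the share of higher calls from 48.6% to 59.4%. In the fit to all arrays the effects in SNB19 and in SF539 called 477 genes in common. Of these 212 were higher in both, 161 lower in both and 104 in opposite directions, where independent lists would share 76.7, 59.6 and 139. Both effects are tested with the same estimate of the spread of each gene, which can itself make calls coincide. The comparisons of each siRNA with scramble in each line shared 79 genes, 45 higher and 34 lower. That count was 5 and 20 without SF539 siRNA1 replicates 2 and 1, 30 without SF539 scramble replicate 1, 191 and 220 without SF539 siRNA2 replicates 1 and 2, and 44 to 47 without any 1 SNB19 array. Fold changes of different lines correlated across genes with r = 0.262 for siRNA1, 0.158 for siRNA2, and 0.187 and 0.211 for different siRNAs.

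**Figure D3:**
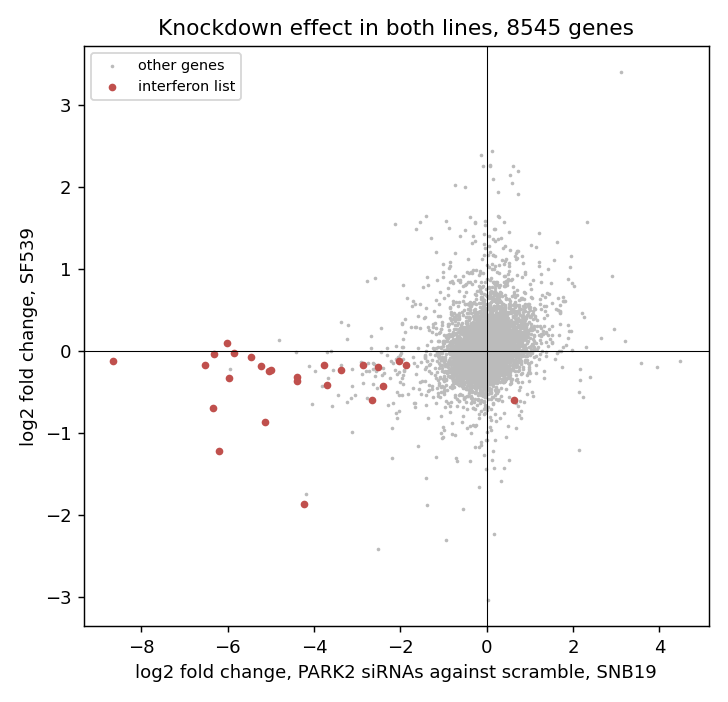
Log2 fold change of the PARK2 siRNAs against scramble in SNB19 on the horizontal axis and in SF539 on the vertical axis for 8545 genes, with the interferon list in red. The interferon list has a median of -4.69 in SNB19 and -0.23 in SF539.

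Whether the lines differ in response was tested as SF539 minus SNB19. The interferon-stimulated genes IFI27, BST2, MX1, IFIT3 and IFIT1 had differences of 8.54, 6.35, 6.28, 6.12 and 5.81. IFIT1 and IFIT3 were at 2.97 and 4.58 in SF539 with scramble, where the lower quartile of the arrays was 3.93 to 4.02, so these genes had little room to fall there. SCRG1, SERPINA3, GFAP, PODXL and ESM1 had differences of -4.60, -4.14, -3.72, -3.35 and -3.07, that of GFAP being -1.85 with the mean of its probe sets. ESM1 was at 2.95 in SNB19 with scramble, below the lower quartile of the arrays, so it had little room to fall there. Of 26 interferon-stimulated genes 25 had a higher and 1 a lower difference (list adjusted p = 2.93e-37, and adjusted p = 0.02 with an estimated correlation). Of 17 hypoxia-induced genes 14 passed with a median of 1.38 (list adjusted p = 1.7e-13, and adjusted p = 0.289 with an estimated correlation), and of 20 glycolysis genes 10 passed (list adjusted p = 1.34e-05, and adjusted p = 0.323 with an estimated correlation). Adjusted over the list alone, 25 interferon-stimulated, 16 hypoxia-induced and 11 glycolysis genes had a higher difference. The response of 1629 genes differed, 920 with a higher and 709 with a lower value in SF539. The count was 952 and 1071 without SNB19 scramble replicates 1 and 2 and 2686 without SF539 siRNA2 replicate 1, and median centring moved the median of all genes to -0.18 and the share of higher calls from 56.5% to 27.6%.

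**Figure D4:**
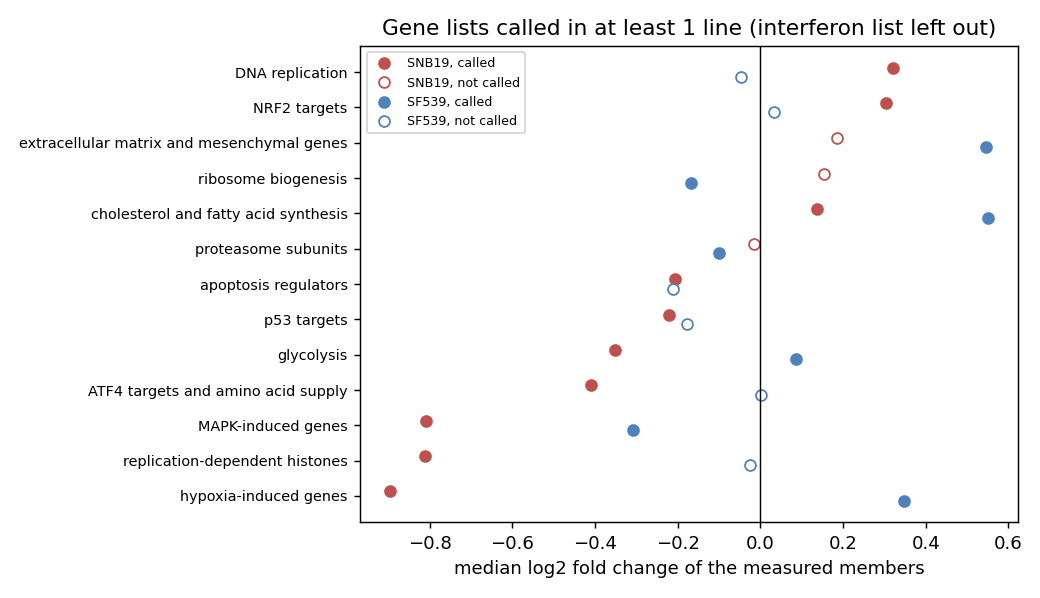
Median log2 fold change of the measured members of each gene list called in at least 1 line, SNB19 in red and SF539 in blue, filled where the list was called. The hypoxia-induced list has a median of -0.90 in SNB19 and 0.35 in SF539.

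The siRNAs were also compared directly. In SNB19, PLN was higher with siRNA2 than with siRNA1 by 2.63 ± 0.16 (limma adjusted p = 2.39e-05), IL11 by 2.55, RPE65 by 2.13, the haem oxygenase gene HMOX1 by 1.99 and RGS4 by 1.98. AKR1B10, CD180, CP, CHI3L2 and STC1 had differences of -3.38, -2.84, -2.16, -2.09 and -1.89. Of 17 hypoxia-induced genes 11 were lower with siRNA2 (list adjusted p = 1.6e-17), of 20 glycolysis genes 6 were lower (adjusted p = 1.29e-07) and of 26 interferon-stimulated genes 7 were higher (adjusted p = 8.83e-07), each with adjusted p = 0.253 with an estimated correlation. In these lists 13 and 10 were lower, and 15 interferon-stimulated genes were higher and 1 lower, adjusted over the list alone. Oxidative phosphorylation, cholesterol, proteasome and NF-kB lists were also called, all higher with siRNA2, with 0, 5, 0 and 4 members passing and 0, 7, 0 and 4 adjusted over the list alone (adjusted p = 3.16e-05, 0.000343, 0.00571 and 0.0063, and adjusted p = 0.773, 0.483, 0.773 and 0.253 with an estimated correlation), the last of them not without SNB19 siRNA2 replicate 2 (adjusted p = 0.0538). In total 518 genes passed, 263 higher and 255 lower. The count was 134 and 176 without SNB19 siRNA1 replicates 1 and 2, 154 and 158 without siRNA2 replicates 1 and 2, 1082 without either SF539 siRNA2 array and 1122 with the 6 SNB19 arrays alone. RGS4 lost its call without any 1 array other than those of SF539 siRNA2 (adjusted p from 0.0563 to 0.186) and with a trended robust prior (adjusted p = 0.0526).

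In SF539, CCL2 was higher with siRNA2 by 3.06 ± 0.33 (limma adjusted p = 0.00497), the transcription factor gene EGR3 by 2.56, VCAM1 by 2.16, CXCL10 by 2.14 and CCN5 by 2.13. MMP1, the anticoagulant receptor gene THBD, IL13RA2, ESM1 and SLC22A4 had differences of -2.73, -1.94, -1.60, -1.54 and -1.41. Without siRNA2 replicate 2 EGR3, VCAM1 and SLC22A4 had differences of 1.46, 1.40 and -0.81. Of 23 cholesterol and fatty acid genes 7 were higher and 1 lower, of 22 ATF4 targets 4 were higher (list adjusted p = 5.94e-08 for both) and of 26 matrix genes 3 were higher (adjusted p = 3.39e-07), each with adjusted p = 0.716 with an estimated correlation. Adjusted over the list alone, 13 cholesterol genes were higher and 2 lower, 11 ATF4 targets were higher, and 14 matrix genes were higher and 1 lower. Hypoxia-induced, lysosome and interferon lists were also called higher, with 3, 1 and 2 members passing and 6, 2 and 3 adjusted over the list alone (adjusted p = 2.94e-06, 0.00975 and 0.0217), and ribosome biogenesis, proteasome, mitosis, DNA replication, oxidative phosphorylation and heat shock lists lower, with 2 members of the first passing and 0 of the others, and 10 and 2 of the first and second adjusted over the list alone (adjusted p = 3.31e-06, 7.46e-06, 0.00101, 0.00396, 0.00624 and 0.018), each with adjusted p = 0.716 with an estimated correlation except oxidative phosphorylation (adjusted p = 0.728). Without siRNA2 replicate 2 the medians of DNA replication, mitosis and oxidative phosphorylation turned from -0.33, -0.32 and -0.15 to 0.027, 0.11 and 0.029, and the proteasome, interferon, lysosome and heat shock calls were lost (adjusted p = 0.102, 0.285, 0.685 and 0.468), the last also without siRNA1 replicate 1 (adjusted p = 0.0773). Replicate 2 exceeded replicate 1 of siRNA2 by a median of 0.41 in ATF4 targets, 1.08 in matrix genes and 0.55 in hypoxia-induced genes. The median differences of these lists, 0.39, 0.84 and 0.38, were 0.13, 0.20 and 0.15 without replicate 2 and 0.65, 1.29 and 0.60 without replicate 1. Those of the proteasome, interferon, lysosome and heat shock lists, -0.21, 0.071, 0.16 and -0.23, were -0.081, 0.021, 0.0063 and -0.024 without replicate 2 and -0.36, 0.16, 0.30 and -0.40 without replicate 1, and DNA replication, mitosis and oxidative phosphorylation had -0.60, -0.81 and -0.31 without replicate 1. In total 232 genes passed, 157 higher and 75 lower. The count was 3 and 26 without SF539 siRNA1 replicates 1 and 2, 148 without either SF539 scramble array, 2303 without siRNA2 replicate 1 and 85 to 99 without any 1 SNB19 array. With the 6 SF539 arrays alone limma called 0 genes, and 1194 had an unadjusted p under 0.05. EGR3 and SLC22A4 lost their calls without any 1 array other than those of SF539 siRNA2 (adjusted p from 0.0587 to 0.192 and from 0.0563 to 0.178), and CXCL10 and ESM1 without any 1 SNB19 array, either siRNA1 array or siRNA2 replicate 2 (adjusted p from 0.0503 to 0.157 and from 0.0694 to 0.203). VCAM1, CCN5 and THBD lost theirs without siRNA1 replicate 1 (adjusted p = 0.151, 0.143 and 0.147) or 2 (adjusted p = 0.0944, 0.0944 and 0.101), and CCL2 without siRNA1 replicate 1 (adjusted p = 0.0878). With array weights EGR3, CXCL10, THBD, ESM1 and SLC22A4 did not pass (adjusted p = 0.0708, 0.123, 0.0659, 0.202 and 0.0551), nor did the interferon list with dim genes left out (adjusted p = 0.0644).

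The lines themselves were compared with scramble. SRGN, which encodes a granule proteoglycan, the collagen gene COL6A3, PLIN2, BASP1 and HTATIP2 were higher in SF539 by 9.08, 8.81, 7.95, 7.8 and 7.19. IFIT1, the osteopontin gene SPP1, EFEMP1, GPM6B and TGFA had differences of -9.90, -9.76, -9.01, -8.37 and -8.15. On the SNB19 arrays IFIT1 was at 12.854 and 12.885 with scramble but from 6.534 to 7.67 with the PARK2 siRNAs. Part of its difference thus goes with the SNB19 scramble arrays alone. With the mean of probe sets PLIN2, HTATIP2 and TGFA had differences of 3.98, 4.40 and -4.03. Of 24 NF-kB and inflammatory genes 15 were higher in SF539 and 3 lower (list adjusted p = 0.00219, and adjusted p = 0.258 with an estimated correlation), and 16 and 3 adjusted over the list alone. The call was lost with dim genes left out (adjusted p = 0.0692). In all 4212 genes passed, 2101 higher and 2111 lower. Median centring moved the median of all genes to 0.20 and the share of higher calls from 49.9% to 66.0%.

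The remaining lists were called in neither line for the PARK2 siRNAs against scramble. In SNB19 and SF539 the adjusted p was 0.722 and 0.942 for mitosis, 0.0741 and 0.339 for oxidative phosphorylation, 0.17 and 0.394 for NF-kB and inflammatory genes, 0.722 and 0.394 for Wnt targets, 0.738 and 0.81 for YAP/TAZ targets, and 0.211 and 0.712 for lysosome and autophagy. It was 0.772 and 0.989 for the unfolded protein response, 0.772 and 0.0911 for heat shock proteins, 0.301 and 0.0911 for the RNA interference machinery and 0.662 and 0.865 for glial genes. For markers of other cell types it was 0.662 and 0.697 (leukocytes), 0.211 and 0.394 (endothelium) and 0.772 and 0.81 (epithelium). The median and the mean differed in sign in SNB19 for the unfolded protein response, heat shock, glial and epithelial lists, and in SF539 for the unfolded protein response, NRF2, histone and glial lists, none of which was called there.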

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

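Of the tests below, those of SF539 RNA or SF539 samples in the SNB19 scramble groups, of an innate response, of PARK2 loss, of fewer cycling cells, of sequence-specific siRNA effects and of splits that keep replicates together were chosen only after the result was seen. The results listed first are those whose response to the PARK2 siRNAs differed between the lines by a test of the difference itself, given as SF539 minus SNB19 on the log2 scale. In all 1629 genes differed.

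Among the genes named for these comparisons, values above 0 were those of IFI27 at 8.54, BST2 at 6.35, MX1 at 6.28, IFIT3 at 6.12, IFIT1 at 5.81, IFITM1 at 5.73, PSMB9 at 5.65, OAS1 at 5.64, IFI44L at 5.38, ISG15 at 5.04, RSAD2 at 4.97, OASL at 4.28, VCAM1 at 2.76, MATN2 at 2.53, ISG20 at 2.44, CXCL10 at 2.36, COL3A1 at 2.35, CCN4 at 2.31, GPR183 at 2.18, DAPK1 at 1.65, SCD at 1.48 and OLFML2B at 1.48. Values below 0 were those of SCRG1 at -4.60, SERPINA3 at -4.14, GFAP at -3.72 (-1.85 with the mean of its probe sets), PODXL at -3.35, ESM1 at -3.07, CRYAB at -3.07, SPARCL1 at -2.71, MMP7 at -2.68, EDNRB at -2.48, IL24 at -2.39, EFHD1 at -2.25, ACO1 at -1.98, MN1 at -1.91, CCL20 at -1.47, IL13RA2 at -1.37, CBX5 at -1.21, PGAP1 at -1.15 and MYLK at -0.91. With scramble IFIT1 was at 2.97 in SF539, and ESM1, CCL20 and IL24 were at 2.95, 3.65 and 3.86 in SNB19, below the lower quartile of the arrays (3.93 to 4.02), so these genes had little room to fall there.

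Of the gene lists, interferon-stimulated genes had a median difference of 4.17 (adjusted p = 2.93e-37, and adjusted p = 0.02 with an estimated correlation). Hypoxia-induced genes had 1.38, histones 0.73, ATF4 targets 0.48, MAPK-induced genes 0.48, p53 targets 0.40 and glycolysis 0.40, and DNA replication had -0.34 and ribosome biogenesis -0.28. Their adjusted p was 1.7e-13, 8.55e-05, 0.000133, 0.0314, 0.0196, 1.34e-05, 0.000116 and 0.00902 in that order, and adjusted p = 0.289, 0.323, 0.593, 0.593, 0.289, 0.323, 0.672 and 0.531 with an estimated correlation. The MAPK call was lost without SNB19 scramble replicate 2 (adjusted p = 0.0657), SNB19 siRNA2 replicate 1 (0.0706), SF539 scramble replicate 1 (0.0559) or SF539 siRNA2 replicate 2 (0.128), and with dim genes left out both the MAPK and the p53 call were lost (adjusted p = 0.17 and 0.199). Median centring moved the median difference of all genes to -0.18 and turned the direction of none of these 9 lists. Without SF539 siRNA2 replicate 2 the DNA replication and ATF4 medians were -0.19 and 0.32, and with dim genes left out the histone median was 2.34.

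Interferon-stimulated genes were high in both SNB19 scramble arrays, with a list median of 10.78 against 5.62 and 6.17 with siRNA1 and siRNA2, and 10.85 in SF539 with scramble. RNA of SF539 cells would have brought other SF539 genes along, but 21 genes at least 6 log2 units higher in SF539 had a median of 0.078 in scramble minus siRNA arrays of SNB19, and of -0.01 over the 16 outside the list. Samples of SF539 under the SNB19 scramble label are argued against by a mean correlation over the 8545 genes tested of 0.976 with SNB19 siRNA arrays and 0.919 with SF539 siRNA arrays, a difference of 0.0571 (over probe sets the means were 0.979 with SNB19 siRNA and 0.933 with all SF539 arrays). An innate response to the scramble siRNA may have raised these genes, or loss of PARK2 may have lowered them, the smaller of the list medians with siRNA1 and siRNA2 being -4.57. These cannot be told apart, since no untransfected sample was among the arrays analysed and the list in SF539, with a median change of -0.23, started 4.58 above the SNB19 siRNA level. A state of the SNB19 scramble samples unrelated to the siRNAs was not tested and stays open too, as the replicates may be technical.

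In SF539 siRNA2, 232 genes differed by over 1 log2 unit between the arrays, against 1 to 49 in the other groups. A larger response of the kind seen with siRNA1 needs at least 60% of the 233 siRNA1 genes to deviate in the siRNA1 direction, and 49.4% did. These genes were called with a spread that includes the difference between these replicates, so genes that differ strongly between them tend to be left out. That share alone therefore cannot decide the question. Over all genes tested, which are not independent replicates, replicate 2 minus replicate 1 correlated with the siRNA1 change with r = -0.0026. No tendency in the siRNA1 direction was thus seen across genes. RNA of SNB19 cells is argued against by 29 genes of SNB19, whose median in replicate 2 minus replicate 1 was -0.054. Array noise in dim genes is argued against by a ratio of deviations in dim to other genes of 0.695, which is 0.362 of the median of the other groups (1.35 to 2.26). In the brighter genes the median absolute difference was 0.216, against 0.0657 to 0.108 in the other groups, and technical variation there was not tested. A culture with fewer cycling cells may account for part of the difference, with all 31 mitosis genes lower in replicate 2 (median -0.85) and a median of -0.55 for DNA replication. It was not tested whether the matrix genes, 24 of 26 higher in replicate 2 with a median of 1.08, go with that state or with another property of the culture.

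The difference between the PARK2 siRNAs was not shared by the lines across the genome. Sequence-specific effects of an siRNA common to both lines would give siRNA2 minus siRNA1 a correlation across genes, which are not independent replicates, but r was 0.00716 (0.0891 without SF539 siRNA2 replicate 2 and -0.0363 without replicate 1). Within a line, differences from separate arrays correlated with r = 0.727 in SNB19 and 0.438 in SF539, so they were partly reproducible between arrays. As the replicates may be technical, this may reflect the samples rather than the siRNAs. It does not show that a shared siRNA effect would have been seen. Both lines called 41 genes, 23 in the same direction and 18 in opposite directions, where independent lists would share 14.06, so effects in few genes or in 1 line stay open. Unequal depletion of PARK2 was not tested, as its level was not analysed here.

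For the 2561 genes called over both lines the arrays were split in other ways within each line. Of 100 splits drawn 1, the real one, gave as many genes, and the highest of the others gave 1755, but most splits part the replicates of a group, which widens the spread and lowers the count by itself. Splits that keep the replicates of each group together number 9, too few for a share under 0.05, and the highest of the others among them gave 1946. That split kept the real scramble arrays of SNB19 in their role, so it still holds the real SNB19 comparison. With an siRNA group in the scramble role in both lines the highest count was 1755.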

How the results depend on the processing

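The choice of alternatives was made before the data were examined, except agreement without the genes of the interferon list and with a scramble array of its own for each siRNA, which were chosen only after the result was seen. Every probe set on its own was not run for gene lists. Genes near the lower quartile of the arrays have little signal over background, which bounds their changes.

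With the replicate number as a block, siRNA1 against scramble in SF539 called 135 genes, siRNA2 against siRNA1 in SF539 called 138 and all 4 siRNA comparisons shared 45. Of the genes named, IL24 with siRNA1 in SF539 (adjusted p = 0.061), ESM1 between the siRNAs in SF539 (0.0764) and PSMD8 in SF539 (0.0728) did not pass, and the block changed no other call of a gene or list the text names. Deviations of arrays with the same number correlated from -0.18 to 0.11, over 0.1 in 1 of 15 pairs, so little effect common to a number was visible. This cannot show that samples with the same number were handled apart. The block spends degrees of freedom (4 left of 6).

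With only the arrays of the line, counts were 165 for SF539, 1 for siRNA1, 308 for siRNA2 and 0 for siRNA2 against siRNA1 in SF539, with 1487, 915, 1870 and 1194 genes at an unadjusted p under 0.05 by limma. SF539 shared 1 gene between the siRNAs, and siRNA2 against siRNA1 in SNB19 called 1122. Fewer samples and a spread set by the line alone are part of this setting. With array weights siRNA1 and siRNA2 in SF539 called 485 and 350, and siRNA2 against siRNA1 called 1427 in SNB19 and 24 in SF539. A trended robust prior gave 375 for the last. Testing every probe set, which tests more features, gave 4679 for SNB19, 1488 for SF539, 4380 over both lines, 3750 and 4219 for siRNA1 and siRNA2 in SNB19, 2134 for siRNA2 in SF539, 2653 for the difference between lines, 7268 between the lines and 2773 shared in SNB19. A 1.5-fold minimum, a stricter rule, left 1186, 319 and 531 for SNB19, SF539 and both lines, 1151 and 1253 for siRNA1 and siRNA2 in SNB19, 130 and 594 in SF539, 282 for siRNA2 against siRNA1 in SNB19, 1045 for the difference, 2628 between the lines, and 813, 103 and 30 shared in SNB19, in SF539 and in all 4.

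With dim genes left out siRNA2 against siRNA1 in SF539 called 356 genes, all 4 comparisons shared 141, and 7 lists were called over both lines. The agreement of fold changes was then 0.902 within SNB19, 0.311 and 0.226 for siRNA1 in SNB19 with siRNA1 and siRNA2 in SF539, and 0.255 and 0.191 for siRNA2 in SNB19 with them. The mean of probe sets gave 0.224 for siRNA2 in SNB19 with siRNA1 in SF539. Without the interferon list the agreement was 0.854 within SNB19, 0.25 for siRNA1 in both lines and 0.192 for siRNA2 in SNB19 with siRNA1 in SF539. With a scramble array of its own for each siRNA, which removes shared array noise and adds that of single arrays, it was 0.841 within SNB19 and 0.46 within SF539. With an estimated correlation 1, 0 and 1 lists were called in SNB19, SF539 and both lines. The cause was not tested for array weights, the prior, dim genes, the mean of probe sets or the interferon list.

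Leaving out each array in turn gave 1741 to 3551 genes for SNB19, 371 to 1973 for SF539, 1948 to 3336 over both lines, 1405 to 3055 and 1593 to 3299 for siRNA1 and siRNA2 in SNB19, and 16 to 802 and 615 to 2593 in SF539. It gave 134 to 1082 and 3 to 2303 for siRNA2 against siRNA1 in SNB19 and SF539, 952 to 2686 for the difference, 3438 to 4694 between the lines, and 1060 to 2317, 14 to 547 and 5 to 220 shared in SNB19, SF539 and all 4. Agreement was 0.866 to 0.887 within SNB19 and 0.501 to 0.748 within SF539, 0.233 to 0.268 and 0.151 to 0.203 for siRNA1 in SNB19 with siRNA1 and siRNA2 in SF539, and 0.184 to 0.222 and 0.111 to 0.196 for siRNA2 in SNB19. Lists called were 11 to 12 in SNB19, 4 to 11 in SF539 (4 without scramble replicate 2) and 10 to 14 over both lines. The lowest counts for SF539 came without SF539 scramble or siRNA1 arrays, and the highest without an SF539 siRNA2 array.

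The direction, for lists that of the test, turned in 4 results when 1 array was left out, and the cause was not tested. The mitophagy list in SF539, not called, had a median of 0.039 without SF539 scramble replicate 1 (-0.075 at the lowest, without replicate 2), and siRNA2 against siRNA1 in SF539 without siRNA2 replicate 2 had medians of 0.027 for DNA replication, 0.11 for mitosis and 0.029 for oxidative phosphorylation, against -0.60, -0.81 and -0.31 without siRNA2 replicate 1. Of the other values, 2658 for named genes kept their direction and side of the threshold over the alternatives, 109 lost their call and 8 gained one, and with 1 array left out 3318 did, 166 lost it and 8 gained one. For gene lists 614 kept the direction of the test and their side of the threshold and 85 lost their call, and with 1 array left out these were 835 and 37. The median of the mitophagy list, not called, turned sign without a turn of the test, from -0.00076 to 0.13 in SNB19 and from -0.017 to 0.026 over both lines with median centring, and also in SNB19 without scramble replicate 1, siRNA1 replicate 2 or siRNA2 replicate 2 and over both lines without either of the first pair.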

Other observations

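Of the tests in this part, the scan of neighbouring genes and those of the single genes named were chosen only after the result was seen. With scramble, the hypoxia, glycolysis and histone lists, which fell in SNB19 with the PARK2 siRNAs, were lower in SF539 than in SNB19. Both comparisons use the same SNB19 scramble arrays, so a state of those arrays alone would appear in both. The histone list averaged 6.92 in SNB19 with scramble and 5.57 and 5.79 with siRNA1 and siRNA2, against 5.59 in SF539 with scramble. The hypoxia averages were 10.60, 9.97, 9.02 and 9.49 in that order, and those of glycolysis 10.29, 10.09, 9.68 and 9.85. Of 17 hypoxia-induced genes 12 were lower and 3 higher, of 20 glycolysis genes 16 were lower and 2 higher, with the glucose transporter gene SLC2A1 at a difference of -2.17, and of 14 replication-dependent histones 8 were lower, H2BC21 by a difference of -3.53 (list adjusted p = 0.00219, 0.00514 and 0.0072, and adjusted p = 0.778, 0.634 and 0.634 with an estimated correlation). The interferon, ATF4, MAPK, p53 and apoptosis lists, which also fell in SNB19, were not called between the lines (adjusted p = 0.92, 0.453, 0.28, 0.287 and 0.825). Glial and cholesterol lists, which did not fall in SNB19, were lower in SF539. Of 16 glial genes 6 were lower, the astrocyte gene S100B by -3.58, and of 23 cholesterol genes 12 were lower and 4 higher (list adjusted p = 0.0106 and 0.0228, and adjusted p = 0.258 and 0.895 with an estimated correlation). The cholesterol call was lost without SF539 scramble replicate 2 (adjusted p = 0.0546), on ranks (0.0544) and with dim genes left out (0.0744). Of 29 DNA replication genes 18 were higher and 3 lower, and of 14 ribosome biogenesis genes 9 were higher (list adjusted p = 0.0095 and 0.00514, and adjusted p = 0.895 and 0.634 with an estimated correlation). Adjusted over the list alone, 12 and 3, 16 and 3, 8 and 0, 6 and 0, and 13 and 4 were lower and higher in the lists first named, and 19 and 3, and 10 and 0 were higher and lower in the last. The cell cycle inhibitor gene CDKN2A was at 10.08 in SF539 and 4.44 in SNB19.

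The Wnt antagonist gene DKK1 changed by -1.18 in SNB19 and -1.29 in SF539 (limma adjusted p = 1.69e-05 and 0.000135), and the chemokine gene CXCL8 by -1.41 and -1.55 (limma adjusted p = 4.56e-05 and 0.000281), although CXCL8 in SNB19 changed by -2.40 with siRNA1 and by -0.43 with siRNA2, which did not pass (limma adjusted p = 0.0721). NT5E, which encodes the ectoenzyme CD73, changed by -3.15 in SNB19 and -0.58 in SF539 (limma adjusted p = 8.22e-08 and 0.0227), and lost its SF539 call without scramble replicate 1 or 2 or siRNA1 replicate 2 (adjusted p = 0.13, 0.0952 and 0.0654) and with the 6 SF539 arrays alone (adjusted p = 0.132). The chemokine gene CCL5 changed by -3.45 in SNB19 (limma adjusted p = 3.1e-05), and its -0.53 in SF539 did not pass. IFNB1 fell in SNB19 too, by 1.39 ± 0.22 (limma adjusted p = 0.00101), from 5.31 with scramble to 3.98 with siRNA1 and 3.87 with siRNA2, near the lower quartile of the arrays.

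A run of neighbouring genes was low in SF539. In the gene order of assembly GRCh38.p14 the 6 SF539 arrays had a mean of 2.94 for MINPP1, 3.08 for PAPSS2, 4.26 for ACTA2, 3.42 for FAS, 3.92 for LIPA, 4.65 for IFIT3 and 2.95 for IFIT1, against 9.48, 7.22, 7.27, 7.58, 10.15, 7.72 and 8.97 over the 6 SNB19 arrays, while LIPF and CH25H were low in both lines. The SNB19 means of IFIT3, IFIT1 and FAS join different states, at 11.73, 12.87 and 8.74 with scramble, 5.57, 6.54 and 7.16 with siRNA1 and 5.86, 7.51 and 6.84 with siRNA2, so IFIT3 with the siRNAs lay closer to SF539. The flanking genes GLUD1, IFIT5 and KIF20B were expressed in SF539, at 9.94, 10.48 and 8.88. Loss of a stretch of DNA may account for this, and was set to be excluded if the lowest median over 5 neighbouring genes lay within the range of shuffled gene orders. That median, -4.17, did lie within it, since 25 of 1000 shuffles of 8167 genes were as low and the lowest reached -5.49. A value that chance can give leaves chance open but does not forbid a loss, so that mark excluded nothing, and expression alone cannot tell a loss from genes that are not expressed.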
